A study of Mus musculus with 10 samples.

How the data were processed

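The series measured messenger RNA in gastrocnemius, the large calf muscle, of male C57BL/6 mice on Affymetrix whole-transcript arrays. Per the labels' protocols, RNA of 5 animals was diluted to 98 ng/µl and pooled for each of the 10 arrays, and sense-strand cDNA was made and labelled with biotin. Animals of the F0 generation had voluntary exercise (EX) or a sedentary life (SED) and were mated with partners of like exposure. Their F1 and F2 descendants were all sedentary, so that EX and SED name their ancestry. F0 animals were 28 weeks old and descendants 8 weeks old when the muscle was taken. F0 EX and F0 SED had 1 pool each, and F1 EX, F1 SED, F2 EX and F2 SED had 2 pools each.

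The authors deposited 1 table of log2 probe set signals, which ran from 0.966 to 14.2 over 35557 probe sets. That the scale is log2 was read from this range. The submitters' processing notes name Affymetrix Expression Console. Its version, the background correction, the normalization, the summarization and a genome build are not given in the sources used here. The medians of the arrays over all probe sets lay between 3.22 and 3.36. The lower quartile was 2.48 in F0 SED and in F1 EX pool 1, and between 2.28 and 2.32 in the other arrays. Values were used as deposited. No detection calls were used, and the number of arrays limits the precision.

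Probe sets were named through GEO's platform annotation, which can be old. It gave 1 gene symbol for 21789 probe sets, several for 1621 and none for 12147. Entrez identifiers of 21698 probe sets matched a RefSeq gene table of assembly GRCm38.p6, which was used for names only, and 0 symbols changed through it. Probe sets with several symbols named no gene. Where a gene had more than 1 probe set (999 of 19938 genes), the probe set with the highest mean over all arrays was taken. Genes with a mean at or above the 40th percentile (3.23 on the log2 scale) were kept, which left 11963.

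Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over the 11963 genes and a threshold of adjusted p 0.05. The F1 ancestry effect, the F2 ancestry effect and their difference came from a model of the 4 descendant groups, fitted to 8 arrays. The ancestry effect over both generations and the difference between F2 and F1 came from an additive model of generation and ancestry on the same arrays. F0 was set against the mean of F1 and F2 in an additive model on all 10 arrays. F0 EX and F0 SED had 1 pool each, so their difference was given by size only, with a bound of 0.5 on the log2 scale, and without a test. A list's median in that comparison was placed among 10000 random lists of the same size matched on mean expression in 10 bins. The labels number the pools of a group without saying that they hold different animals. The series' design text speaks of 10 males per ancestry, which, if meant for each generation, would be 2 pools of 5 different animals. The p-values measure only the spread between these pools, which may be technical.

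Gene lists, 31 in number, were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except where another time is stated. They covered fibre types, energy metabolism, signalling, matrix, vessels, other cell types, clock, growth and imprinting. Lists with at least 5 kept members (28) were tested with camera at its preset correlation of 0.01, and with camera at an estimated correlation and fry as alternatives. The lists of mitochondrially encoded genes (2 kept members), lymphocyte markers (3) and erythrocyte markers (4) were too small to test. Text examples are the 10 largest called changes per direction in which the arrays of the groups did not overlap, filled to 5 with the smallest p where fewer passed, up to 4 members of each list and a fixed set of muscle genes. For the F0 pools they are the 10 highest and the 10 lowest differences. Genes with no characterised product were counted but need not be named.

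The fits were tested on simulated data, in which genes were changed by 0.5, 1 or 2 on the log2 scale. In each comparison 54 to 79 genes of each size were changed together. For ancestry over both generations, 52.2%, 91.2% and 98.5% of such genes were recovered among 11963. The shares were 3.7%, 66.7% and 100% for F1 ancestry, 5.2%, 73.0% and 93.7% for F2 ancestry, and 0%, 14.5% and 80.6% for the difference of both effects. They were 40.5%, 88.3% and 98.5% for F2 against F1, and 33.3%, 83.8% and 100% for F0 against descendants. Many large changes ease the Benjamini-Hochberg threshold for small ones. With few changed genes, changes of 0.5 or 1 would thus be recovered less often than these shares. The extracellular matrix list, raised by 0.3 in the simulated ancestry comparison, had a camera adjusted p of 1.31e-22, and 0 other lists were called. Simulated genes were drawn independently, so this could not check the preset correlation. In the real ancestry comparison the estimated correlation of that list was 0.344. Simulated arrays also had equal spread, whereas F1 EX pool 1 deviated from the other descendant arrays with an SD of 0.331, against 0.153 to 0.193 for the others.

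Alternatives were quantile normalization of the table, median centring, no filter on low values, a filter at the 60th percentile, the average of a gene's probe sets, eBayes with trend and robust settings, array quality weights, the replicate number as a block, each pool left out in turn, and other sets of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.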

Results

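The data were 10 arrays of mouse gastrocnemius RNA, each hybridised with a pool from 5 males. The study's design compared muscle of exercised and sedentary F0 animals, and of 2 generations of sedentary descendants from each ancestry. F0 EX and F0 SED had 1 pool each, and F1 EX, F1 SED, F2 EX and F2 SED had 2 pools each. Values are log2 probe set signals as deposited, and differences are on the log2 scale.

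Most arrays resembled each other closely, and a pair of them stood apart. The F0 SED array had a median Pearson r of 0.974 with the other 9 arrays, across the 11963 genes kept, and F1 EX pool 1 had 0.979. For the other arrays the median r lay between 0.986 (F0 EX) and 0.993. The pools of F1 EX differed from each other by 0.5 or more in 1830 of 11963 genes, against 316 in F1 SED, 279 in F2 EX and 344 in F2 SED. No columns held identical values.

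**Figure D1:**
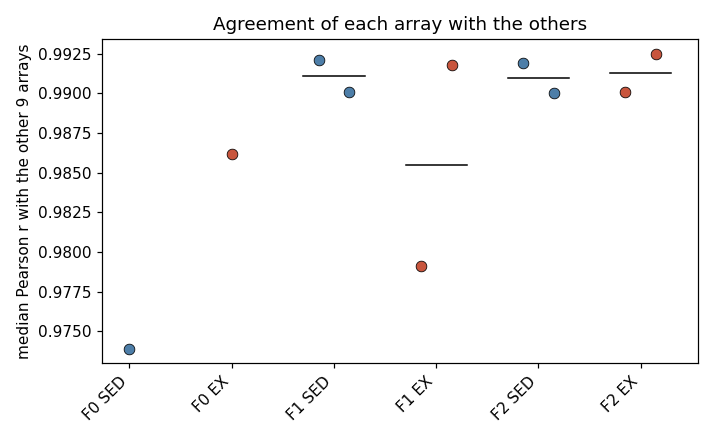
Median Pearson r of each array with the other 9 arrays (vertical axis, no unit) by group, 1 point per pool, with a line at the mean where a group had 2 pools. The F0 SED array (0.974) and F1 EX pool 1 (0.979) lie lowest.

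The first comparison was of exercised and sedentary F0 animals, the generation that was itself exposed. Genes of fatty acid oxidation, the tricarboxylic acid cycle and slow fibres had larger differences between the F0 EX and F0 SED pools than most random lists. Pdk4, a kinase that restrains pyruvate dehydrogenase, was 1.02 higher on the log2 scale, and the fatty acid transporter Cd36 was 1.12 higher. Hadha of the mitochondrial trifunctional protein was 1.10 higher and Etfdh, which passes electrons from fat oxidation to ubiquinone, 1.11 higher. Ppargc1a, a coactivator of mitochondrial genes, was 0.76 higher, citrate synthase (Cs) 0.55, slow myosin Myh7 0.68, slow troponin Tnnc1 1.17 and fast myosin Myh1 0.72. The fatty acid uptake and oxidation list had 12 of 28 members higher by at least 0.5 and 1 lower. Its median of 0.45 lay at percentile 98 of random matched lists, whose own median was 0.27. The heat shock list had a median of 0.45 (percentile 98), the slow fibre list 0.40 (percentile 95.8) and the tricarboxylic acid cycle list 0.46 (percentile 94.7). The random lists matched to these had medians of 0.21, 0.19 and 0.29. Part of each list's difference was thus shared by genes of like expression. The random lists were drawn without regard to correlation between genes, and the percentiles of the 28 lists were not adjusted. In the model on all 10 arrays the estimated correlation was 0.32 for the fatty acid list and 0.50 for the tricarboxylic acid cycle list. It was 0.25 for the slow fibre list and 0.09 for the heat shock list. The percentiles are therefore no measure of chance. The fast fibre list had a median of 0.22 (percentile 25.3), which was -0.03 with quantile normalization, and 1 of its 18 members, Myh1, higher by 0.5. The list of mitochondrial biogenesis regulators, to which Ppargc1a belongs, had a median of 0.14 (percentile 33.3). Nuclear-encoded oxidative phosphorylation genes, 59 in number, had a median of 0.28 at percentile 42, and 0 with quantile normalization. Matrix genes lay at the other end, with a median of -0.11 for the extracellular matrix list (percentile 0, 3 of 34 members higher by 0.5 and 4 lower). The tendon and cartilage list had a median of -0.19 and the immediate early list -0.18, both at percentile 0.3. For the matrix, tendon and immediate early lists the matched random lists had medians of 0.19, 0.13 and 0.06. Their low percentiles thus came in part from the rise of genes of like expression. Mean deviations from the mean over 10 arrays lay close, at -0.72 in F0 EX and -0.68 in F0 SED for matrix genes. They were -0.51 and -0.44 for tendon genes. Timp1 differed by -0.68 and Col4a1 by -0.62, while Fn1 differed by 0.77 and Dcn by 0.65.

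In all, 1835 genes were higher in F0 EX by at least 0.5 and 644 lower. Among the largest differences were Krtap5-3 (2.33), Stox2 (1.81), Styx (1.75), Alb (1.71), Pdcd10 (-1.75), Macrod2 (-1.65) and Tubb2b (-1.5). With 1 pool per group there was no replicate check of any of these values. The array medians differed by 0.119, and with each array centred on its median the counts were 1197 higher and 1162 lower, and with quantile normalization 1112 and 989. The medians of the fatty acid, tricarboxylic acid cycle, heat shock, slow fibre and matrix lists were then 0.33, 0.35, 0.33, 0.28 and -0.23 with centring, and 0.17, 0.19, 0.21, 0.22 and -0.28 with quantile normalization. Tricarboxylic acid cycle genes had a mean deviation of -0.37 in F0 SED and 0.10 in F0 EX, which lay within the descendant pools (-0.12 to 0.14), and heat shock genes had -0.20 in F0 SED and 0.17 in F0 EX (descendants -0.12 to 0.12). Fatty acid genes had -0.23 in F0 SED and 0.19 in F0 EX (descendants -0.12 to 0.12), and slow fibre genes -0.18 and 0.22 (-0.12 to 0.23). The F0 SED array, which stood apart from the rest, was the lowest of all 10 arrays in 1384 of the 1835 genes.

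The next comparison asked whether sedentary F1 sons of exercised parents differed from F1 sons of sedentary parents. Fat genes had the largest mean difference among the lists, while the median was -0.22 for them and -0.23 for myeloid markers. Cidec, a lipid droplet protein, differed by -0.91 (SE 0.166), Fabp4 by -0.78, adiponectin (Adipoq) by -1.05 and the desaturase Scd1 by -1.05, each from 2 pools against 2. The adipocyte and lipogenesis list had a mean of -0.31, with 19 of 24 estimates below 0, and camera gave an adjusted p of 2.75e-04. The macrophage and other myeloid list had a mean of -0.28 (adjusted p = 1.58e-03), with Lyz1 at -0.59 and Cd74 at -0.92. The interferon-stimulated list had a mean of -0.22 (adjusted p = 7.26e-03), with Usp18 at -0.53 and Irf7 at -0.44, and the tendon and cartilage list a mean of -0.15 (adjusted p = 0.043), with Kera at -0.41 and Chad at -0.38. For each of these lists the adjusted p was 0.954 with an estimated correlation. None of their members passed over all genes, and adjusted over the list alone 2 passed in the adipocyte list and 1 in the interferon list.

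No gene passed in F1 with limma. The smallest adjusted p was 0.804, and 584 genes had an unadjusted p under 0.05, where chance gives 598. The median 95% confidence interval reached 0.33 either side of the estimate. The genes with the smallest p among separated ones, none of which passed, included Mrgpre (0.72), Gcsh (0.68), Wipf1 (0.63), Tulp1 (0.62), Atp10d (0.57), Trim30a (-0.65) and the clock gene Arntl (-0.63). Without F1 EX pool 2 the group was represented by pool 1 alone, the array that stood apart, and 1046 genes passed on the assumption that a lone pool varies like the others. All 4 list calls ended in that fit, with means of -0.29 for adipocyte (camera adjusted p = 0.124), -0.28 for myeloid (0.174), -0.14 for interferon (0.390) and -0.12 for tendon genes (0.387). Without F1 SED pool 1, 8 genes passed, and the means of the myeloid and interferon lists were -0.46 (camera adjusted p = 1.03e-09) and -0.42 (8.94e-10). Without F1 SED pool 2 the calls of the myeloid (mean -0.09, adjusted p = 0.769), interferon (-0.02, 0.944) and tendon (-0.15, 0.264) lists ended. The tendon call also ended with quantile normalization (mean -0.14, 0.0628) and with the filter at the 60th percentile (-0.16, 0.0721), as did the interferon call with that filter (mean -0.17, 0.520). Without a filter the mean of the interferon list was -0.15 (5.99e-03).

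In F2, the grandsons, the same comparison placed matrix, tendon and slow fibre genes higher in EX. Among matrix genes Thbs1 was estimated 0.41 higher in EX, Mmp14 0.35 and the proteoglycan Bgn 0.32, and 31 of 34 matrix genes had estimates above 0. The extracellular matrix list had a mean of 0.20 and a camera adjusted p of 7.29e-08. All 15 tendon and cartilage genes had estimates above 0, with Chad at 0.51 and Col11a1 at 0.43 (list mean 0.29, adjusted p = 5.25e-07). Slow fibre genes had a mean of 0.21 (adjusted p = 6.69e-04), with slow troponin T (Tnnt1) at 0.37, Myl3 at 0.29 and Myh7 at 0.30. The fatty acid uptake and oxidation list had a mean of 0.13 (adjusted p = 0.0109), with Acaa2 at 0.33 and Cpt2 at 0.28. With an estimated correlation the adjusted p was 0.469 for the matrix, tendon and slow fibre lists and 0.828 for the fatty acid list. Without F2 EX pool 2 the mean of the tendon list was 0.17 (adjusted p = 0.0498) and that of the matrix list 0.13 (0.0309), and without F2 SED pool 1 that of the matrix list was 0.12 (8.05e-03).

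No gene passed in F2 with limma, where 532 genes had an unadjusted p under 0.05 and the median confidence interval again reached 0.33 either side. Glrx3, a glutaredoxin of iron-sulfur cluster handling, had the smallest p of the named genes (0.79, SE 0.139, adjusted p = 1). Others were Maoa (0.71), Sestd1 (0.54), Cpz (-0.80), Kbtbd11 (-0.69) and Krtap17-1 (-0.66), with Ppp1r3c, a glycogen-targeting subunit, at -0.67 and Arntl at -0.39. The call of the slow fibre list ended without F2 SED pool 1 (mean 0.13, adjusted p = 0.0724), and that of the fatty acid list without F2 EX pool 1 (mean 0.08, 0.425), without F2 SED pool 2 (0.07, 0.670) and with quantile normalization (0.08, 0.0609). With centring its mean was 0.08 (0.0116).

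The difference between the F2 and F1 ancestry effects was tested directly. Tendon and cartilage genes had a mean difference of 0.44 with 14 of 15 estimates above 0. The camera adjusted p was 5.70e-07, and it was 0.726 with an estimated correlation. Chad differed by 0.89 (SE 0.202) and Kera by 0.67, and adjusted over the list alone 2 genes passed. Over all genes none passed with limma, with 519 at an unadjusted p under 0.05, and Glrx3 had an estimate of 1.20 (adjusted p = 0.919). Without F1 EX pool 2 there were 143 genes past the threshold, and without F1 SED pool 1 there were 5. The myokine list was called by fry alone (adjusted p = 0.0208), with a camera adjusted p of 0.376.

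**Figure D2:**
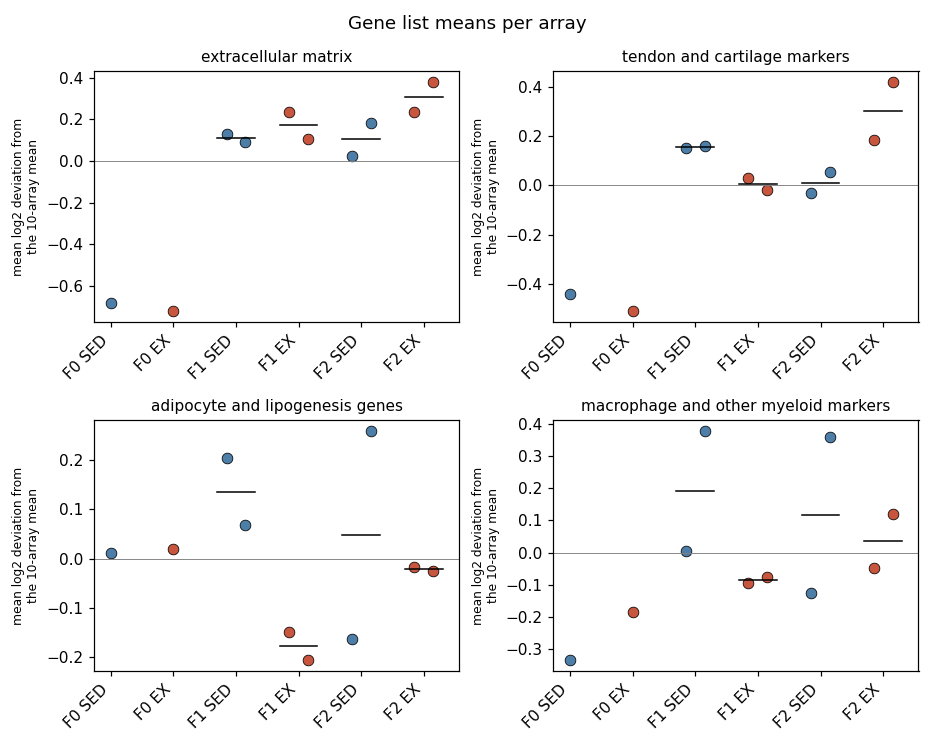
Mean log2 deviation of each gene list from the mean over 10 arrays (vertical axis) by group, 1 point per pool, with a line at the mean where a group had 2 pools. The extracellular matrix list lies at -0.72 in F0 EX and -0.68 in F0 SED, below all descendants.

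Over both generations, 4 EX pools were set against 4 SED pools. Ppp1r3c differed by -0.56 (SE 0.114), from 8.29 ± 0.18 in EX to 8.86 ± 0.25 in SED (SD, n = 4 each), and Arntl, a core clock transcription factor, by -0.51 (SE 0.113). Others with the smallest p were Myo1d (0.41), Maged1 (0.38), Srpx2 (0.43), Nova1 (0.39), Icam2 (0.38), Fndc10 (-0.45), Fam43b (-0.44) and Pdxp (-0.55). None passed, with an adjusted p of 0.888 for each. Matrix genes had a mean of 0.13, with 31 of 34 estimates above 0 (camera adjusted p = 7.37e-07), and included Mmp14 at 0.34, Col1a1 at 0.23 and Col3a1 at 0.23. Adipocyte genes had a mean of -0.19 (adjusted p = 1.42e-04), with Cidec at -0.55 and Scd1 at -0.71. Myeloid genes had a mean of -0.18 (adjusted p = 1.30e-03), with C1qa at -0.24 and Cd74 at -0.64, and interferon-stimulated genes a mean of -0.12 (adjusted p = 0.0305). With an estimated correlation the adjusted p was 0.941 for the myeloid list and 0.935 for the other called lists. In F1 alone the matrix list had a mean of 0.06 (camera adjusted p = 0.103). The adipocyte, myeloid and interferon lists were called in F1 and not in F2. Their F2 means were -0.07 (camera adjusted p = 0.184), -0.08 (0.315) and -0.01 (0.645). Mean deviations of adipocyte genes were -0.16 and 0.26 in the F2 SED pools, either side of -0.02 and -0.03 in the F2 EX pools.

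Genes commonly followed in exercised muscle had small estimates. Ppargc1a had an estimate of 0.07 with a 95% interval from -0.19 to 0.33, and the glucose transporter Slc2a4 had 0.04 (-0.15 to 0.23). Cs had -0.11 (-0.32 to 0.09). Slow myosin Myh7 had 0.29 (0.06 to 0.51) at an unadjusted p of 0.0167 and an adjusted p of 0.888. No gene passed with limma, 597 genes had an unadjusted p under 0.05, and 99.6% of genes had an interval within 1 either side of 0. The count was also 0 with trend and robust settings and with array weights. The myeloid and interferon calls ended without F1 SED pool 2 (means -0.09 and -0.02, adjusted p = 0.210 and 0.867), without F2 SED pool 2 (means -0.10 and -0.12, adjusted p = 0.106 and 0.067) and without F1 EX pool 2 (-0.16 and -0.06, 0.0525 and 0.317). The interferon call also ended with quantile normalization (mean -0.11, adjusted p = 0.0997), without a filter (-0.07, 0.0981), with the filter at the 60th percentile (-0.15, 0.0996) and with the F0 pair included (-0.06, 0.111). Without F2 SED pool 1 the mean of the matrix list was 0.09 (adjusted p = 2.06e-03) and that of the adipocyte list -0.30 (7.76e-11). The mean of the myeloid list was then -0.30 (9.93e-09), and it was -0.11 (6.72e-03) with the F0 pair included. That of the interferon list was -0.17 (1.75e-04) without F1 SED pool 1.

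Between F2 and F1, which were of the same age, Nmrk2, a kinase of nicotinamide riboside salvage in muscle, had the smallest p. It stood at 7.78 ± 0.11 in F2 and 6.68 ± 0.42 in F1 (SD, n = 4 each), a difference of 1.10 (SE 0.139, limma adjusted p = 0.111). Cardiac actin Actc1 had a difference of 0.41, Mybph 0.45 and Cdkn1c 0.41, while Mss51 had -0.66, Htra4 -0.50, Spns2 -0.42 and Npnt -0.40. Slow fibre genes had a mean of 0.17 (camera adjusted p = 1.35e-03), with Csrp3 at 0.52, Casq2 at 0.47 and Myl2 at 0.40. Nuclear-encoded oxidative phosphorylation genes had a mean of 0.07 (adjusted p = 1.35e-03) and tricarboxylic acid cycle genes 0.09 (adjusted p = 6.31e-03). The myogenic and developmental list had a mean of 0.10 (adjusted p = 5.97e-03), with Mymk at 0.49 and Myog at 0.34, and the imprinted list 0.13 (adjusted p = 6.80e-03), with Zim1 at 0.57, Mest at 0.51 and Igf2 at 0.38. Adjusted over the list alone, 4 members passed in each of the last pair and 2 slow fibre genes. As written, the myogenic and imprinted lists share Dlk1, H19, Igf2 and Peg3. The oxidative phosphorylation and tricarboxylic acid cycle lists share Sdha, Sdhb, Sdhc and Sdhd, so that these calls are not independent. With an estimated correlation the adjusted p was 0.650 for slow fibre, 0.665 for oxidative phosphorylation and tricarboxylic acid cycle, and 0.573 for the myogenic and imprinted lists.

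No gene passed between F2 and F1 with limma, with 509 at an unadjusted p under 0.05. With trend and robust settings 2 genes passed, Nmrk2 (adjusted p = 0.0300) and Actc1 (0.0360), and with array weights 1 did, Nmrk2 (0.0126). The tricarboxylic acid cycle call ended without F1 EX pool 1 (mean 0.05, adjusted p = 0.104), without F2 EX pool 1 (0.07, 0.0583) and with quantile normalization (mean 0.06, 0.0868), where the oxidative phosphorylation list had a mean of 0.05 (0.0249). Without F1 EX pool 2 the oxidative phosphorylation (mean 0.05, adjusted p = 0.0648), myogenic (0.07, 0.0782) and imprinted (0.12, 0.0648) calls ended, and without F2 SED pool 2 the imprinted call (0.10, 0.0880).

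The last comparison set F0 animals, 28 weeks old, against their descendants, 8 weeks old. Collagen and matrix genes were lower in F0. Col1a1 had signals of 9.51 in F0 EX and 9.56 in F0 SED, against 11.8 ± 0.16 in descendants (SD, n = 8), and was 4.84-fold lower (limma log2 difference -2.27, SE 0.117, adjusted p = 1.47e-06). Col1a2 fell by 1.88, the matricellular protein Sparc by 1.61, Col3a1 by 1.5, the collagen-degrading protease Ctsk by 1.41 and Postn by 1.31. Of 34 extracellular matrix genes 24 were lower and none higher, and adjusted over the list alone 31 were lower. The list's median was -0.79 (camera adjusted p = 1.25e-37, and adjusted p = 0.0472 with an estimated correlation). Of 15 tendon and cartilage genes 9 were lower, among them Kera (-1.09), Tnmd (-1.02), Cilp2 (-1.0) and Fmod (-0.90). The list's adjusted p was 2.91e-08, and 0.258 with an estimated correlation.

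Some genes of developing muscle were also lower in F0. Actc1, the actin of developing muscle and heart, was 5.89-fold lower (log2 difference -2.56, SE 0.188) and Mybph 5.92-fold lower. Wif1, a secreted Wnt inhibitor, fell by 1.76, Ccnd1 by 1.04 and Igf1 by 0.60. Of 24 myogenic and developmental genes 4 were lower and 1 higher (camera adjusted p = 1.40e-03, adjusted p = 0.124 with an estimated correlation, and 0.0888 without F0 EX, where the mean was -0.32 against -0.28 over all arrays). Of 10 cell cycle and growth genes none passed (median -0.05, camera adjusted p = 0.665). Imprinted genes were lower in 6 of 22, with none higher, among them Mest (-1.06), Igf2 (-0.93), Peg3 (-0.80) and Grb10 (-0.80). Their list had a camera adjusted p of 4.86e-05, and 0.0645 with an estimated correlation. Igf2 and Peg3 also belong to the myogenic list, so that the calls of both lists are not independent. Of 26 endothelial genes 5 were lower, among them the apelin receptor Aplnr (-0.99), Pecam1 (-0.71), Cdh5 (-0.62) and Ptprb (-0.58), with an adjusted p of 4.06e-05, and 0.0472 with an estimated correlation. Alb, with the largest fall (-2.85), also varied widely among descendants (7.65 ± 1.31, SD, n = 8).

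Higher in F0 was Mss51, a muscle mitochondrial protein, at 9.67 in F0 EX and 9.98 in F0 SED against 7.19 ± 0.45 in descendants (SD, n = 8), which is 6.22-fold (limma log2 difference 2.64, SE 0.129, adjusted p = 1.47e-06). The kainate receptor partner Neto2 rose by 2.28, Slc15a5 by 1.87, Ostn, the secreted peptide osteocrin, by 1.75 and Rasd2 by 1.70. Keratinocyte genes were among the largest rises, with Krt5 at 2.07, Krt10 at 1.63, Krtdap at 1.55 and Krt77 at 1.47. Their signal was higher in F0 SED than in F0 EX, with Krt5 at 5.73 and 4.55. By these values Krt5 lay below the expression bound of 3.23 in descendants, so that it was kept for testing through its F0 signal. In the insulin signalling list 2 genes were higher and 2 lower of 27, with Slc2a3 at 1.37, Tbc1d4 at 0.52, Grb10 at -0.80 and Irs1 at -0.60. Of 28 antioxidant genes 2 were higher and none lower, Nqo1 (0.93) and Gpx3 (0.73), with a list adjusted p of 0.237. Phospholamban (Pln, 1.11) was the only gene to pass of 30 calcium handling genes (list adjusted p = 0.0879) and of 16 slow fibre genes (0.859). Of 35 DNA methylation and histone modifiers 2 were lower and none higher, Tet3 (-0.73) and Dnmt3a (-0.56), while 19 had estimates above 0 (list adjusted p = 0.981).

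**Figure D3:**
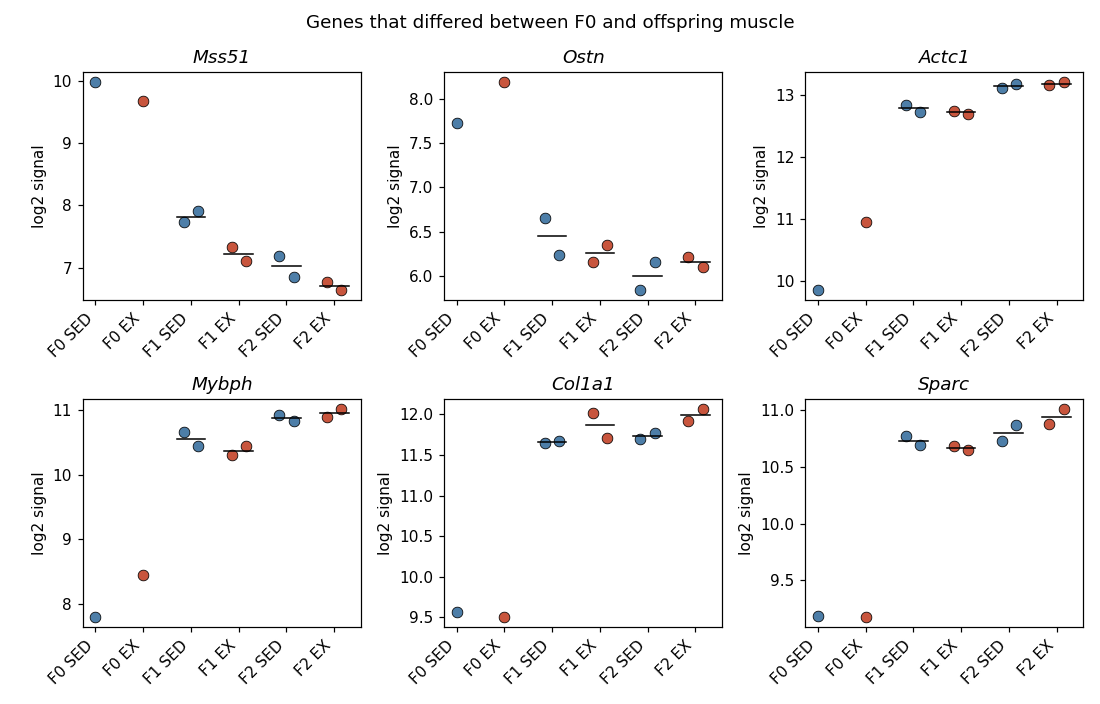
Log2 signal (vertical axes) of 6 genes by group, 1 point per pool, with a line at the mean where a group had 2 pools. Mss51 and Ostn lie higher in both F0 pools than in all 8 descendant pools, and Actc1, Mybph, Col1a1 and Sparc lie lower.

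In all, 95 genes were higher and 184 lower in F0, and 2106 genes had an unadjusted p under 0.05. Age, generation and, for F0 EX, the animals' own exercise went together in this comparison. The count of 279 was 86 without the F0 SED array (71 of them shared), 1231 without F0 EX, 584 without F1 EX pool 1, 185 without F2 EX pool 2 and 181 without F2 SED pool 2. It was 38 with array weights and 14 against F1 only, all of them shared. The fits without F0 SED or without F0 EX rest on a single F0 pool, and assume that it varies like the others. Without F0 EX that pool was F0 SED, the array that stood apart. Of the genes named in this comparison Mss51, Neto2, Slc15a5, Ostn, Actc1, Mybph, Wif1, Col1a1, Col1a2, Col3a1 and Sparc passed against F1 only, and the others did not. With array weights Rasd2, Krt10, Krtdap, Ctsk, Postn, Igf2, Tnmd, Cilp2, Aplnr, Ccnd1 and Slc2a3 passed as well, while Krt5, Krt77, Alb, Igf1, Peg3, Mest, Grb10, Kera, Fmod, Pecam1, Cdh5, Ptprb, Irs1, Tbc1d4, Pln, Tet3, Dnmt3a, Gpx3 and Nqo1 lost their call. Without F0 SED and F1 EX pool 1 together, a choice made after seeing the data, it was 170, with 111 shared. In that fit Col1a1, Actc1, Mybph and Mss51 passed, and Krt5, Krt10, Krt77, Alb, Igf1, Grb10, Fmod, Pecam1, Ptprb, Irs1, Tbc1d4, Pln, Tet3 and Dnmt3a did not. These genes, with Mest, Kera and Cdh5, also lost their call without F0 SED alone, and Cdh5, Pln, Gpx3 and Nqo1 did so without F0 EX. Ptprb and Cdh5 lost it without several of the descendant pools, and Tbc1d4 without F2 EX pool 2. Without both arrays the mean of the matrix list was -0.95 (camera adjusted p = 4.49e-41). The mean of the oxidative phosphorylation list, -0.15 over all arrays (camera adjusted p = 2.68e-04, and adjusted p = 0.5 with an estimated correlation), was -0.04 (0.0731), and it was -0.05 (0.104) without F0 SED alone, -0.26 (9.43e-04) without F0 EX and -0.07 (0.0432) with quantile normalization.

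The EX minus SED differences were set against each other across 11963 genes, which are not independent replicates. Pearson r was -0.30 between F0 and F1 (Spearman -0.28), 0.18 between F0 and F2 (Spearman 0.19) and 0.04 between F1 and F2 (Spearman 0.04). Without F1 EX pool 1 the first was -0.01, and without F1 SED pool 1 it was -0.19. Without F2 EX pool 1 that between F0 and F2 was 0.11, and with quantile normalization 0.10. With the F1 arrays split in the other ways, r with F0 was -0.35 and -0.20, so that a split across ancestries gave a larger size than the real one. With the F2 arrays split in the other ways, r with F0 was 0.11 and 0.04. Other splits gave up to 0.13 in size between F1 and F2.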

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

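The test on tendon content and the correlation with F1 EX pool 1 were chosen after the result was seen, and the baseline from pairs of descendant arrays was added after the percentages it is set against.

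The tendon and cartilage list was marked because the F2 and F1 ancestry effects differed by 0.442 in its mean. When the arrays of each generation were split 2 against 2 in all 9 ways, 1 split, the real one, gave a difference as large, and the highest of the others was 0.32. With 9 splits no share can fall under 0.05. Pools may vary in tendon content whatever their ancestry, and these splits leave this open. An effect of ancestry that differs between generations also stays open.

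Probe sets without a single gene name were not part of the comparisons. Of 4810 such probe sets above the expression bound, 6 passed in F0 against descendants, 1 higher and 5 lower.

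The difference between the F0 pools is the pattern with the least replication. In genes higher in F0 EX by 0.5, F0 SED was the lowest of 10 arrays in 75.4%, as an array that lies apart would give, and F0 EX the highest in 51.1%, just past the 50% named in advance for own exercise. Choosing genes by a difference between arrays favours both outcomes, and among 56 ordered pairs of descendant arrays none reached 75.4% while 22 reached 51.1%, so that the latter value says little. F0 SED was the only sedentary pool of 28 weeks, and the descendant pairs were all of 8 weeks. The former value therefore cannot tell an odd array from age. Across all genes the F0 difference had an r of -0.372 with the deviation of F1 EX pool 1, and at most 0.277 in size with any other descendant array, so F0 SED may share a deviation with that array. After regression on that deviation 1613 genes were higher and 579 lower, and own exercise stays open with 1 pool per group.

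Keratinocyte genes were among the largest rises in F0. A list of 23 other epidermal markers, written before the test, had a median F0 difference of 0.451, between the bounds named in advance for skin or hair carried over (above 0.5) and against it (below 0.1). The median was 0.623 for F0 SED and 0.254 for F0 EX, and 18 of 23 markers lay above 0. Their median level in descendants was 2.84, below the expression bound of 3.23, and of the 4 most abundant Trp63 (5.27 in descendants) differed by 0.67, Perp (3.67) by -0.02, Sfn (3.54) by 0.07 and Krt14 (3.52) by 0.45. Carry-over may contribute, and a difference with age was not tested.

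Other splits of the samples were refitted for each comparison of many genes. For ancestry over both generations, 8 of 34 splits, the real one among them, gave at least the real 597 genes at an unadjusted p under 0.05. The highest other gave 1834, in a split where F1 EX pool 1, the array that stood apart, alone faced the other F1 pools. A split with 2 pools of each generation on either side, as in the real one, still gave 907, so chance cannot be excluded. For F2 against F1, 13 of 34, again with the real one among them, gave as many as the real 509. The highest other gave 1692, in a split where F1 EX pool 1 alone faced the other EX pools. A split with 2 pools of each ancestry on either side still gave 764, so again chance cannot be excluded. For F0 against descendants, 2 of 45 choices of 2 arrays gave as many called genes as the real 340 (in a model with ancestry alone beside it), a share under 0.05. The other choice was F0 SED with F1 EX pool 1, which gave 2022 genes, several times the real count, and so points to a structure of the samples that the groups do not describe.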

How the results depend on the processing

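The fit without F0 SED and F1 EX pool 1, and the regression of the F0 difference, were chosen after seeing the data; the cause of the changes below was not tested unless stated.

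The count of 0 genes for F2 ancestry and for ancestry over both generations held under every alternative run. With pools left out in turn, the F1 count ranged from 0 to 1046, the count for the difference of effects from 0 to 143, and F0 against descendants from 86 to 1231. The last count was 38 with array weights, 2255 with sedentary ancestry only, 14 against F1 only, 242 against F2 only and 170 without F0 SED and F1 EX pool 1. F2 against F1 had 2 genes with trend and robust settings and 1 with array weights.

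The replicate numbers did not pair the pools: deviations of same-numbered pools correlated at 0.016 in F1 and 0.064 in F2. With the replicate number as a block, 0 genes passed in each of the 5 comparisons of descendants.

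Camera called 4 lists in F1, 4 in F2, 1 for the difference of effects, 4 for ancestry over both, 5 for F2 against F1 and 13 for F0 against descendants. With an estimated correlation it called 0 in each, except 2 for F0. Fry called 0, except 1 for the difference of effects and 7 for F0.

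Genes higher and lower in F0 EX by 0.5 were 1835 and 644 (74% higher) as deposited, 1112 and 989 (52.9%) with quantile normalization, and 1197 and 1162 (50.7%) with centring. The lower count was 1578 without a filter and 264 at the 60th percentile, where the number of genes differs.

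The correlation between F0 and F1 was -0.382 at the 60th percentile and ranged from -0.349 to -0.012 with pools left out. F0 against F2 was 0.101 with quantile normalization and ranged from 0.109 to 0.200. F1 against F2 ranged from -0.002 to 0.050, turning sign without F1 EX pool 1.

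Of 2505 values of named genes 5 changed sign and 132 were no longer called. Only genes called in the main fit, all of them in F0 against descendants, could lose a call. The 2505 also hold values of the other comparisons, so they are no base for a share of lost calls. For ancestry over both generations, Ppargc1a was -0.01 with averaged probe sets and Cs 0.02 with the F0 pair included. Ppargc1a and Slc2a4 turned without F1 SED pool 2 and Pdk4 without F2 SED pool 2. With pools left out Ppargc1a ranged from -0.01 to 0.15, Slc2a4 from 0.00 to 0.07 and Pdk4 from -0.03 to 0.17. Of 511 list values 4 changed direction and 61 were no longer called. The F1 interferon list ranged from -0.419 to -0.025, with camera's direction turned without F1 SED pool 2. In F0 against descendants the fast fibre list was 0.024 with quantile normalization, and the tricarboxylic acid cycle list ranged from -0.412 to 0.074 with pools left out, highest without F0 SED, and was 0.034 without F0 SED and F1 EX pool 1. The number of arrays limits precision, and signal over background was not given.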

Other observations

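No test in this part was chosen after its result was seen, except the fit without F0 SED and F1 EX pool 1.

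Several other gene groups differed between F0 and descendants by camera alone. Myeloid markers had a median of -0.33, with 23 of 24 estimates below 0 and no member past the threshold (adjusted p = 6.07e-05). Fast fibre genes had a median of -0.15 (adjusted p = 0.0288), tricarboxylic acid cycle genes -0.19 (0.0218), smooth muscle and pericyte markers -0.17 (0.0213) and immediate early genes -0.14 (0.0239). The insulin signalling list had a median of 0.16 (0.0292) and the circadian list 0.18 (0.0303). With an estimated correlation the adjusted p was 0.5 for the myeloid, smooth muscle, immediate early, insulin and circadian lists, 0.601 for fast fibre and 0.644 for the tricarboxylic acid cycle. All of these calls except that of the myeloid list ended without an F0 pool. Over all arrays the means were -0.17 for smooth muscle, -0.17 for immediate early, 0.09 for insulin and 0.10 for circadian genes. Without F0 EX they were -0.14 (adjusted p = 0.437), -0.07 (0.927), 0.06 (0.113) and 0.04 (0.313). Without F0 SED the mean was -0.03 for fast fibre genes (0.375), 0.12 for insulin (0.146) and 0.17 for circadian genes (0.0538), and the adjusted p for the tricarboxylic acid cycle was 0.375. Against F1 only the fast fibre (mean -0.12, 0.126), tricarboxylic acid cycle (-0.12, 0.126), immediate early (-0.13, 0.109), insulin (0.09, 0.0562) and circadian (0.07, 0.109) calls ended, and against F2 only that of smooth muscle (-0.16, 0.0573). The immediate early call also ended without F1 EX pool 1 (mean -0.13, 0.0706) and, as did the circadian call, with the filter at the 60th percentile (0.0591 for both), the insulin and circadian calls without a filter (0.0657 for both) and with quantile normalization (0.0638 and 0.0761), and the tricarboxylic acid cycle call with quantile normalization (mean -0.07, 0.247). The mean of the myeloid list, -0.32 over all arrays, was -0.16 (0.0180) without F0 SED and -0.49 (3.47e-03) without F0 EX. Without F0 EX that of the fast fibre list was -0.27 (0.0283) and that of the tricarboxylic acid cycle list -0.41 (2.15e-04), and without F0 SED that of the immediate early list was -0.27 (9.91e-05). The mean of the tricarboxylic acid cycle list turned from -0.17 to 0.07 without F0 SED and to 0.03 without F0 SED and F1 EX pool 1, and that of the fast fibre list from -0.15 to 0.02 with quantile normalization (adjusted p = 0.703). Nerve and Schwann cell markers were called by fry alone (adjusted p = 0.0234, camera adjusted p = 0.134). So was the myokine list (fry adjusted p = 0.00666, camera adjusted p = 0.265), in which 1 of 22 members was higher and 4 were lower.

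A hypothesis was that F1 and F2 differ along the axis that separates F0 from descendants, since Mss51 and Actc1 stood out in both comparisons. Over the 279 genes called in F0 against descendants, the F0 difference had a Pearson r of -0.581 with the F2 minus F1 difference, and 195 genes (69.9%) had opposite signs. These genes include Mss51 and Actc1, and over all 11963 genes r was -0.257. Of 35 splits of the 8 descendant arrays, 2 gave an r as large in size, the other being 0.585, so the share was not under the 5% named in advance. That other split set F1 EX pool 1, both F2 EX pools and F2 SED pool 2 against the rest. It is the real split with F1 EX pool 1 and F2 SED pool 1 exchanged, so it is not free of the generation difference. F2 may lie farther from F0 than F1 does, but the splits leave this open. The same genes had an r of -0.331 with the EX minus SED difference.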
